A study of Mus musculus with 4 samples.

How the data were processed

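The series holds 4 RNA libraries from mouse ileum, 1 for each of a fed control and a fasted library at 48 h and at 72 h. Per the labels' protocols, the tissue was flash frozen and total RNA was taken with a miniprep kit. Complementary DNA was primed with random hexamers, tailed, ligated to adaptors, amplified by PCR and made into single-stranded circles. Per the series design text, each fasted library was prepared and sequenced with its own fed control, so each ratio was taken within its pair. The labels do not say how many animals went into a library, at what time of day tissue was taken, or the sex. Genes of the Y chromosome had reads or FPKM above 0 in all 4 libraries. Xist had 2 reads in each count library and no value in the 72 h pair, so these values do not settle the sex there.

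For the 48 h pair the authors deposited whole read counts per gene symbol, not normalized. Rows that name no gene carry the counters that a read counter writes. In the fed control and the fasted library, 36.0% and 36.6% of the sum of all rows had no feature, 30.8% and 30.2% had no unique alignment and 0.258% and 0.260% were ambiguous, and these were kept out of the library totals. Reads given to genes were 33.0% and 32.9% of these sums. Because reads without a unique alignment were not given to genes, members of near-identical families are uncertain in this pair. Gene rows written as NA, 1912 and 2135, were read as 0, since no gene row was written as 0. The 20 genes with most reads took 9.11% and 11.1% of gene reads. For the 72 h pair the authors deposited FPKM per gene with Entrez gene identifiers and positions, per the file headers. Per the submitters' processing notes the tools were Bowtie2, HISAT and RSEM and the build was mm10, without versions or roles. Counter settings, strand and annotation are not given in the sources used here. Genes listed at 0 FPKM were 991 and 1141. Low FPKM values of short genes with 1 listed transcript were close to whole multiples of 1 fragment. They lay within 0.15 of a whole number for 81.2% of 154 genes and 82.4% of 125 genes. The value of 1 fragment was chosen on these same genes, so these shares are partly built in. On a transcript of 1000 bp 1 fragment was worth 0.0548 and 0.0555 FPKM. Estimated depth thus differed little within that pair. PCR copies without molecular identifiers are not independent molecules. Intervals and floors take each read as independent, so the intervals may be too narrow even for the counting error of molecules. Neither covers any other error.

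Symbols were matched to a reference gene table. Of 22756 gene rows in the count files, 19333 symbols were found and 604 were renamed through a synonym, and 24 rows whose symbol had been turned into a date were not named. Of 17389 genes with FPKM, 17348 identifiers were found, and 27 symbols turned into dates were recovered through them. The pairs share 16199 symbols. Positions of the 72 h files are on mm10. Hes1 (Entrez 15205) lies on chromosome 16 from 30065357 to 30067796, Reg3g (Entrez 19695) on chromosome 6 from 78466269 to 78468874, and Reg3b (Entrez 18489) on chromosome 6 from 78370885 to 78373466. Gsdmc2, Gsdmc3 and Gsdmc4 lie on chromosome 15 between 63824346 and 63912297, Mt2 and Mt1 on chromosome 8 between 94172618 and 94180327, and Duox2 and Duoxa2 on chromosome 2 between 122280437 and 122302885. Values are per whole gene, so no exon or untranslated region is singled out.

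Values were scaled within each pair by a trimmed mean of M values, with 30% trimmed on the log ratio and 5% on the level, unweighted. Log2 ratios, fasted over fed, were taken after adding a pseudocount of 1 CPM or 1 FPKM. A gene entered if its higher library had at least 20 reads or 1 FPKM. It was counted as higher or lower at an absolute log2 ratio of 1. For counts, an exact conditional binomial 95% interval of the ratio was computed without the pseudocount, so at low counts the log2 ratio can lie at or beyond an end of it. A count of 0 was set to a floor of 3 counts per library for a lower bound of the fold. No test over genes was run, because 1 library per group gives no spread between replicates. A list's median was set against 10000 random lists of the same size matched on mean level in 10 bins, which describes these libraries and is not a p-value. Lists with fewer than 3 measured members were not placed, which was the case for 1 list at 48 h. For the comparison of the fed controls, counts were divided by the maximum transcript length that the FPKM files list for the gene and by the library total.

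Genes, lists and alternatives were fixed before the data were examined. The text names 10 fixed genes (Hes1, Atoh1, Lyz1, Ang4, Mmp7, Reg3b, Reg3g, Muc2, Olfm4 and Lgr5), the 8 genes highest and 8 lowest in each pair with at least 20 CPM or 10 FPKM in the higher library, without predicted genes or receptor segments, and the 8 highest and 8 lowest in both pairs by the smaller ratio. It also names up to 4 members with the largest absolute ratio in each list it describes, and in the same way members of lists given as further observations. Of 45 fixed lists, those outside the central 95% of random lists in either pair are described, with the Paneth, antimicrobial, goblet, Notch, stem cell and proliferation lists in any case, which makes 37. Some genes that the rule selects are not reported here. Any gene named outside this rule is said to be chosen after its values were seen.

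The alternatives were scaling by library total or by the median of ratios, a pseudocount of 0.1, no floor, a floor 5 times higher (100 reads or 5 FPKM), leaving out multi-copy families and, for the overlap, thresholds of 1.5-fold and 4-fold. Removing a cubic trend of the log2 ratio with transcript length and GC content was added after the data were seen, with both properties taken from the longest GENCODE M21 transcript of each gene. Of genes past the floor, 99.2% and 99.8% had both values. The steps were tested on simulated data, with counts drawn around the mean of each pair, known changes in some genes and the most abundant genes lowered. Scaling, direction of the known changes and list positions were recovered for most changed genes, and few unchanged genes were counted as different. The known changes were put in genes above a set number of reads or estimated fragments, which is not the FPKM floor. They were all past 2-fold and equally many in each direction. The simulation thus does not decide between the scalings. The simulation holds counting noise and no differences between animals. Computing used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.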

Results

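RNA from the ileum, the last segment of the small intestine, was sequenced in wild-type C57BL/6 mice at postnatal day 21. The mice were fed or had been fasted for 48 h or 72 h. Each fasted library had its own fed control, prepared and sequenced with it, so the series holds 4 libraries in 2 pairs, with 1 library per group. The 48 h pair was deposited as read counts per gene. The fed control had 7933952 reads given to genes and the library fasted for 48 h had 7957171. The 72 h pair was deposited as FPKM, with sums of 601957 and 578631 over 17389 genes. The series asks how nutrient sensing by the intestinal epithelium bears on mucosal antimicrobial defence, with translational control of Hes1 in its title. The libraries measured RNA levels and hold no measure of translation. With 1 library per group no difference has a replicate check, so sizes are given and no gene was tested. Intervals in parentheses after the ratio of a gene are 95% counting intervals of the ratio between 2 libraries. They cover the counting error of reads taken as independent, and no other error. Those after a list median or a difference of list medians are 95% bootstrap intervals over genes, unless random lists are named. They measure no spread between animals. A gene is called higher or lower at a log2 ratio of 1 or more in size, which is 2-fold. A gene list is called higher or lower when its median lies outside the central 95% of random lists, called the band. The band need not centre on 0, and at 72 h it ran from -0.05 to 0.50 for oxidative phosphorylation. A median close to 0 can thus be called lower. Random lists were drawn gene by gene, so the band is too narrow for lists whose genes vary together.

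After 48 h of fasting the fixed lists for fatty acid oxidation, gluconeogenesis and lipid absorption had medians above the band, and those for antimicrobial defence, fibroblasts and matrix, and proliferation had medians below it. Mt2, a metallothionein that binds zinc, went from 33 to 1096 reads, a log2 ratio of 4.91 (4.73 to 5.78). Pck1, a rate-limiting enzyme of gluconeogenesis, went from 430 to 3688 reads (log2 ratio 3.25). Reg3g, a C-type lectin that kills Gram-positive bacteria, went from 27703 to 9228 reads (log2 ratio -1.41, interval -1.44 to -1.37). Hes1, a transcriptional repressor downstream of Notch, had 194 and 186 reads, a log2 ratio of 0.11 whose interval ran from -0.18 to 0.41. Of 13911 genes past the level floor, 530 were at least 2-fold higher and 456 at least 2-fold lower in the fasted library.

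Among the genes with the largest increases at 48 h were Mt2, Mt1, Apod, Pdk4, Pck1, Cyp3a11 and Cyp2b10. Mt1 had a log2 ratio of 3.37, Apod of 3.36 and Pdk4, which blocks glucose oxidation, of 3.34. The cytochromes P450 Cyp3a11 and Cyp2b10 stood at 3.20 and 3.17. Among the 8 genes with the largest decreases were 3 neighbouring gasdermin C genes on chromosome 15. Gsdmc4 went from 932 to 8 reads and Gsdmc2 from 425 to 5 reads, while Gsdmc3 went from 292 to 0 reads and was at least 86.1-fold lower against a floor of 3 counts. The counting interval of its log2 ratio reached up to -6.12. These 3 genes are near copies of each other, so their separate values are uncertain. Pla2g4c, a phospholipase A2, went from 909 to 13 reads. Duox2, an epithelial oxidase that makes hydrogen peroxide, and its maturation factor Duoxa2 had log2 ratios of -2.95 and -2.56. Duoxa1, which lies beside Duoxa2 in the genome and was listed at 0.07 and 0.32 FPKM in the 72 h pair, stood at -2.54, and the amino acid transporter Slc6a14 at -2.71.

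Epithelial antimicrobial and mucosal defence genes were lower at 48 h as a group. Of 17 measured members 8 were at least 2-fold lower and 2 at least 2-fold higher, with a median log2 ratio of -0.90, below all 10000 random lists matched on level. Without the multi-copy families, which include the Reg3 and Sprr2a genes, the median was -0.86 over 12 genes and still below the band. Besides Duox2 and Duoxa2, the acute-phase gene Saa1 went from 719 to 111 reads and Saa2 from 55 to 0 reads, at least 16.2-fold lower against the same floor, with an interval reaching up to -3.67. Reg3b, a lectin related to Reg3g, had a log2 ratio of -1.16 (-1.19 to -1.14). The Paneth cell list had a median of -0.31 over 20 members, with 4 lower and 1 higher, outside the central 95% of random lists. Without the multi-copy families its median was -0.15 and inside that band. Among the genes fixed beforehand, Lyz1, the Paneth cell lysozyme, had a log2 ratio of -0.16, Ang4 of -0.34 and Mmp7, the protease that activates defensins, of 0.72. The pentraxins Mptx1 and Mptx2 stood at -2.47 and -1.70, and the defensins Defa26 and Defa35 at -1.43 and 2.08. Alpha-defensins are near-identical copies whose reads cannot be assigned with certainty, and reads summed over 16 of them went from 73050 to 48568, a log2 ratio of -0.41. The sum leaves out reads without a unique alignment, so it is not the total of alpha-defensin RNA.

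Goblet, Notch and stem cell lists had medians inside the central 95% of random lists at 48 h. Of 19 goblet cell genes 1 was higher and 1 lower, with a median of 0.09. Muc2, the main intestinal mucin, had a log2 ratio of 0.30, Agr2, which folds it, of -1.44, and Guca2a, the precursor of guanylin, of 1.35. The 21 Notch and secretory lineage genes had a median of 0.11, with 1 member lower, which was Olfm4. This list mixes Notch targets with ligands, receptors and secretory factors, so its median is no measure of Notch activity. Scaling by library total turned the goblet median to -0.09 and the Notch median to -0.06. It also turned Hes1 to -0.06 and Atoh1 to -0.10. Atoh1, the factor that sets the secretory fate, had a log2 ratio of 0.08 in the scaling used elsewhere. The 20 stem cell genes had a median of -0.08, which was -0.23 and below the band with the floor 5 times higher. Lgr5 stood at 0.34 and Olfm4, a crypt base marker, at -1.26 (-1.34 to -1.19). All 25 proliferation genes had log2 ratios below 0, with a median of -0.47, and 2 were at least 2-fold lower, Mki67 at -1.48 and Top2a at -1.21.

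Lists for fatty acid oxidation, gluconeogenesis, lipid absorption, digestion and amino acid transport had medians above the band at 48 h, while glycolysis and oxidative phosphorylation were inside it at 0.02 and 0.13, or -0.15 and -0.05 with library totals. Of 28 genes for fatty acid oxidation and ketogenesis 11 were at least 2-fold higher, with a median of 0.77, among them Angptl4, an inhibitor of lipoprotein lipase, at 2.78 and Acot1 at 2.63. All 21 lipid absorption genes had log2 ratios above 0 and 7 were at least 2-fold higher, with Apoa4 going from 7484 to 49448 reads and Fabp1 from 300 to 1864. In gluconeogenesis 5 of 11 genes were higher, with a median of 0.87, including Fbp1 at 2.55 and G6pc at 2.19. Enterocyte digestion and absorption genes had a median of 0.54, with 5 of 21 higher, led by the sugar transporters Slc2a5 at 2.89 and Slc2a2 at 2.79. Of 14 amino acid and peptide transporters 4 were higher, with Slc6a19 at 1.88 and Slc7a8 at 1.87. FoxO and glucocorticoid targets had 9 of 20 members higher, including Fkbp5 at 2.29 and Sgk1 at 1.97, and xenobiotic metabolism genes 9 of 22, including Gstm1 at 1.84. Fatty acid synthesis genes were lower, with 7 of 16 at least 2-fold lower and a median of -0.62, among them Scd2 at -2.30 and Scd1 at -1.45.

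Smaller group differences at 48 h ran in both directions. The amino acid response list had a median of 0.36, with Trib3 at 1.96, Ddit4 at 1.27 and Nupr1 at -1.14. The median was 0.19 and inside the band once a trend with transcript length and GC content was removed. Circadian clock genes had a median of 0.40 and 5 of 18 members higher, with Hlf at 1.40 and Usp2 at 1.21. Endoplasmic reticulum folding genes had a median of -0.46, although Herpud1 stood at 1.09. Cytosolic ribosomal protein genes had a median of 0.22 with 9 of 67 higher and 4 lower, from Rplp1 at 1.61 to Rps16 at -2.08. These genes have many processed copies, and their median was 0.15 and inside the band after the trend was removed.

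Markers of other cell types differed in direction at 48 h. Of 22 T cell and intraepithelial lymphocyte genes 4 were higher and 1 lower, Cd2 at -1.10, with a median of 0.56, and the chemokine Ccl5 and granzyme genes Gzma and Gzmb stood at 1.56, 1.42 and 1.28. All 8 class II antigen presentation genes were above 0, or 7 of 8 with library totals, with a median of 0.79, H2-Aa at 1.22 and Cd74 at 1.01. B cell and plasma cell genes had a median of -0.66 with 6 of 18 lower, including Cr2 at -1.74 and Bank1 at -1.41. Fibroblast and matrix genes had a median of -0.90 with 8 of 19 lower, with the collagen genes Col3a1 at -2.05 and Col1a1 at -1.85. All 15 smooth muscle genes were below 0, with a median of -0.60. Tuft cell genes had a median of -0.62 with 3 of 12 lower, including the regulator Rgs13 at -1.25 and Dclk1 at -1.12. Adipocyte genes had a median of -0.72, with Car3 at -2.08 and Adipoq at -1.87, while Cidec stood at 1.24. The endothelial median was 0.32, and was inside the band at 0.03 after the trend was removed and at 0.26 with the higher floor. The interferon response median was -0.30 with 1 of 27 genes lower, Ifi44 at -1.33. The inflammatory list had a median of 0.37 over 10 genes, with Ccl20 at 1.06 and Socs3 at 1.04, and was inside the band at 0.02 over 18 genes without a floor and at 0.28 with the higher floor. The mast cell median was -0.89 over 4 genes, and -0.22 over 7 genes and inside the band without a floor. The exocrine pancreas median was 0.58 over 5 genes, and inside the band under 5 of 7 alternatives, such as 0.29 over 9 genes without a floor. The pancreas list includes Zg16, also a goblet cell product, at 0.58.

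Log2 ratios had a rank correlation across genes of -0.24 with transcript length and 0.34 with GC content at 48 h, and of 0.11 and 0.08 at 72 h, and genes are not independent replicates. Scaling by library total shifted the median log2 ratio of all genes to -0.17 and gave 339 higher and 745 lower, so 31.3% of differing genes were higher instead of 53.8%. List medians shifted with it, to 0.36 for digestion and absorption, 0.24 for the circadian clock, 0.20 for the inflammatory list, 0.18 for the amino acid response, 0.15 for endothelium, 0.04 for ribosomal proteins, -0.26 for stem cells, -0.29 for cholesterol synthesis, -0.48 for interferon response and -0.49 for Paneth cells. Members at least 2-fold higher were then 6 of 20 for FoxO and glucocorticoid targets, 3 of 18 for the clock, 2 of 21 for the amino acid response, 1 of 8 for class II and 0 for the inflammatory and endoplasmic reticulum folding lists. Members at least 2-fold lower were then 2 each for goblet cells, interferon response and smooth muscle and 1 each for endoplasmic reticulum folding, cholesterol synthesis, glycolysis and oxidative phosphorylation. Ribosomal proteins had 6 higher and 6 lower.

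**Figure D1:**
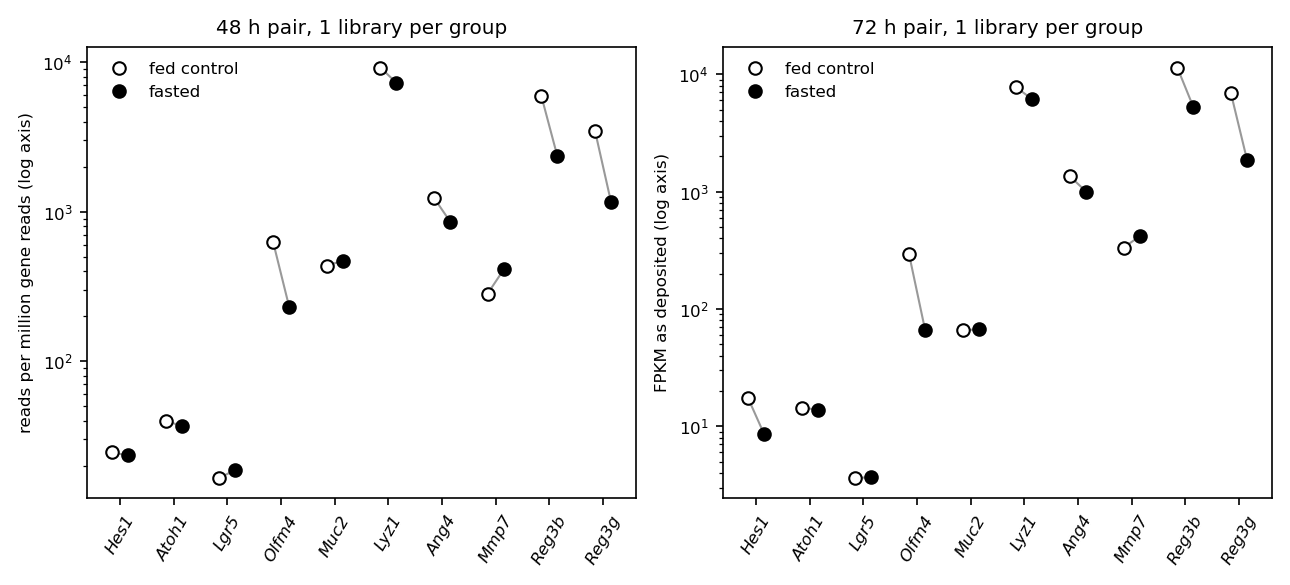
Levels of the 10 genes fixed before the data were examined, in CPM (reads scaled to the library's gene reads) for the 48 h pair and in FPKM for the 72 h pair, both on log axes, with open points for fed controls and filled points for fasted libraries, 1 library each. These levels were not scaled further within a pair. Reg3g, Reg3b and Olfm4 lie lower in both fasted libraries, and Lyz1, Ang4 and Atoh1 do so by less. Hes1 lies slightly lower in the 48 h pair and lower in the 72 h pair, at 8.57 against 17.4 FPKM.

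After 72 h of fasting the lists for gluconeogenesis, FoxO and glucocorticoid targets, lipid absorption and the circadian clock had medians above the band, and those for interferon response, antimicrobial defence and cholesterol synthesis had medians below it. Mt2 went from 7.22 to 1091 FPKM (log2 ratio 7.29), Pdk4 from 1.89 to 236 FPKM (6.57) and Pck1 from 22.75 to 1088 FPKM (5.77). Reg3g went from 6870 to 1862 FPKM (-1.63), and Hes1 from 17.4 to 8.57 FPKM, a log2 ratio of -0.71, or -0.94 as deposited, neither of which reached 2-fold with the pseudocount. Without the pseudocount the deposited Hes1 values lay slightly more than 2-fold apart. Of 12462 genes past the floor, 748 were at least 2-fold higher and 747 at least 2-fold lower. Folds of the 72 h pair are on the scale of log2 of FPKM plus 1, which understates differences of low genes.

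Other genes with large increases at 72 h were Mt1 at 5.08, Nr1d1 at 4.73, Cyp3a11 at 4.53, Hoga1 at 4.27 and Rab30 at 4.09. Nr1d1, which encodes the clock repressor REV-ERB alpha, went from 3.03 to 90.65 FPKM. The largest decreases were those of Gsdmc4 at -5.57, the apolipoprotein L genes Apol10a at -5.39 and Apol7c at -3.73, Gsdmc2 at -4.75, Duoxa2 at -3.75, Sprr2a2 at -3.70 and Batf2 at -3.49. Gsdmc3 was at 18.63 FPKM in the fed control and was listed at 0 in the fasted library.

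Of 19 antimicrobial and mucosal defence genes 10 were at least 2-fold lower at 72 h and 1 was higher, with a median of -1.04. Several Sprr2a and Reg3 genes count separately in this list. Without the multi-copy families the median was -0.77 over 13 genes and still below the band. Sprr2a3, a small proline-rich protein of the epithelium, went from 1439 to 116 FPKM, and Duox2 had a log2 ratio of -3.19. Reg3b stood at -0.87, and at -1.12 when the deposited values were taken as they are. The Paneth cell median was -0.07 over 36 genes, with 6 lower and 3 higher. It lay just below the random band, and inside it without a floor (-0.04), without multi-copy families (-0.13) and after the length and GC trend was removed (0.014). Lyz1 stood at -0.08, Ang4 at -0.17 and Mmp7 at 0.58, while Mptx2 was at -2.81 and Mptx1 at -1.66. Defa28 stood at -1.91 and Defa35 at 2.03. FPKM summed over 31 alpha-defensin genes, against 16 in the 48 h sum, gave a log2 ratio of 0.03, or -0.22 as deposited. The direction of the sum thus depended on the scaling.

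The goblet, Notch and stem cell medians were again inside the central 95% of random lists, at -0.17, 0.20 and 0.06. Agr2 stood at -1.82 and Spink4 at -0.98, while Muc2 was at 0.28. Among 20 Notch and secretory lineage genes 3 were lower and 1 higher, and the median of this mixed list is again no measure of Notch activity. Nrarp, a Notch target, went from 15.36 to 3.61 FPKM, a log2 ratio of -1.61, with Olfm4 at -1.88, Bhlha15 at -1.14 and Sox9 at 1.06. Atoh1 stood at 0.19, and at -0.05 as deposited. The stem cell list held 3 higher and 2 lower of 20, with Clu at 1.08, Rnf43 at 1.07, Ascl2 at -1.21 and Lgr5 at 0.22. As deposited, the Notch and stem cell medians were -0.02 and -0.14. Of 25 proliferation genes 24 were below 0 and 4 were at least 2-fold lower, while Rrm2, chosen after its value was seen, was at 1.06, with a median of -0.78, among them Ccnd1, a G1 cyclin, at -2.56, Mcm5 at -1.28 and Mcm3 at -1.13.

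Lists for gluconeogenesis, lipid absorption, fatty acid oxidation, digestion and amino acid transport had medians above the band at 72 h, and glycolysis a median below it. In gluconeogenesis 6 of 11 genes were higher, with a median of 2.11, including G6pc at 3.74 and Slc37a4 at 2.42. FoxO and glucocorticoid targets had 16 of 20 members higher and a median of 1.91, with Zbtb16 at 3.97, Klf15 at 3.58 and Fkbp5 at 2.97. All 22 lipid absorption genes were above 0, or 19 of 22 as deposited, and 14 at least 2-fold higher, with Apoa4 at 2.95, Fabp1 at 2.62 and Abcg8 at 2.32. Fatty acid oxidation and ketogenesis had 12 of 28 higher and 2 lower, with a median of 0.46 and Angptl4 at 3.97. Digestion and absorption genes had 10 of 21 higher and 1 lower, with a median of 0.92, and weaned-type enterocyte genes 5 of 7, with a median of 1.28 and sucrase-isomaltase, Sis, at 1.28. Sis, Treh, Mgam and Slc2a5 of the weaned-type list are also in the digestion list, and Fabp6 and Slc10a2 in the bile acid list. The weaned-type median is thus not a separate observation. At 48 h the weaned-type median was 0.54 and inside the band. It was above the band without a floor, at 0.51, and after the length and GC trend was removed, at 0.86. Amino acid and peptide transporters had 5 of 14 higher, with Slc6a19 at 2.58 and the peptide transporter Slc15a1 at 1.78. Xenobiotic metabolism genes had 10 of 22 higher and 1 lower, with Abcb1a at 2.41. Autophagy and lysosome genes had 4 of 21 higher, with a median of 0.47 and Bnip3 at 2.03.

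Cholesterol synthesis and endoplasmic reticulum folding genes were lower at 72 h. Of 26 cholesterol synthesis genes 10 were at least 2-fold lower, with a median of -0.94, Idi1 at -1.76, Hmgcs1 at -1.53 and Sqle at -1.52. At 48 h the same list had a median of -0.11 with none past 2-fold. Endoplasmic reticulum folding genes had 10 of 19 lower, with a median of -1.01, Pdia4 at -2.02 and Creld2 at -1.94, while Herpud1 stood at 2.77. Fatty acid synthesis had 2 of 16 lower, Scd2 at -2.40 and Elovl6 at -1.72, and a median of -0.23 inside the band, which was -0.34 and below it with the higher floor. Glycolysis genes had a median of -0.27, with Khk at 1.21 and Pklr at -1.23. Oxidative phosphorylation genes had a median of -0.09 with none of 29 past 2-fold, and were inside the band without multi-copy families (-0.08) and after the trend was removed (-0.01). All 78 ribosomal protein genes were above 0, or 77 of 78 as deposited, with none past 2-fold, and their median was 0.61.

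Circadian clock genes had 9 of 18 members higher at 72 h, with a median of 1.06. Besides Nr1d1, Cry2 stood at 2.90, Tef at 2.83 and Per1 at 2.75. All 27 interferon response genes were below 0 and 17 at least 2-fold lower, with a median of -1.24, Isg15 at -2.46, Ifit1 at -2.32 and Oasl2 at -2.27. B cell and plasma cell genes had 9 of 16 lower, with a median of -1.05 and Ms4a1 at -1.83. All 8 class II genes were below 0, with a median of -0.76, and Ciita, their master activator, stood at -1.83. The T cell median was -0.26 and inside the band, with 2 of 22 lower, among them Gzmb at -1.58, and Ccl5 at 0.98. Fibroblast and matrix genes had 6 of 19 lower, with a median of -0.65, Col1a1 at -2.59 and Col3a1 at -2.41. The smooth muscle median was -0.61, with Cnn1 at -1.15. Endothelial, enteric neuron and enteroendocrine medians were higher, at 0.58, 0.57 and 0.57, with Flt1 at 0.91, Uchl1 at 0.92 and Chga at 1.20. The enteric neuron median was inside the band without a floor, at 0.16 over 18 genes, and with the higher floor, at 0.61 over 5 genes. The tuft cell, adipocyte, exocrine pancreas, amino acid response and inflammatory medians were inside the band, at -0.18, 0.22, 0.31, -0.29 and -0.47, with the adipocyte median at -0.02 as deposited. The amino acid response median was below the band with the higher floor, at -0.44, and without a floor, at -0.29, as was the inflammatory median without a floor, at -0.18. The mast cell median was 0.73 over 3 genes, was 0.19 over 9 genes without a floor, and was inside the band at 0.80 with a pseudocount of 0.1.

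Taking the deposited FPKM as they are shifted the median log2 ratio of all genes to -0.22 and gave 449 higher and 1291 lower genes, so 25.8% of differing genes were higher. List medians shifted with it, to 0.38 for amino acid transport and enteroendocrine cells, 0.36 for ribosomal proteins, 0.34 for endothelium, 0.22 for autophagy, 0.21 for fatty acid oxidation and 0.06 for exocrine pancreas. They shifted to -0.33 for Paneth cells, -0.34 for oxidative phosphorylation, -0.37 for tuft cells, -0.40 for goblet cells, -0.44 for T cells, -0.47 for fatty acid synthesis, -0.51 for glycolysis and -0.52 for the amino acid response. Members at least 2-fold lower were then 13 of 25 for proliferation, 16 of 26 for cholesterol synthesis, 5 of 18 for glycolysis, 3 of 20 for stem cells and 4 each for goblet cells, T cells, class II and smooth muscle. They were 2 of 18 for the clock and 1 each for oxidative phosphorylation, tuft cells, the inflammatory list and weaned-type enterocytes. Members at least 2-fold higher were then 1 of 21 for autophagy and none for the proliferation, stem cell, Notch and enteroendocrine lists.

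**Figure D2:**
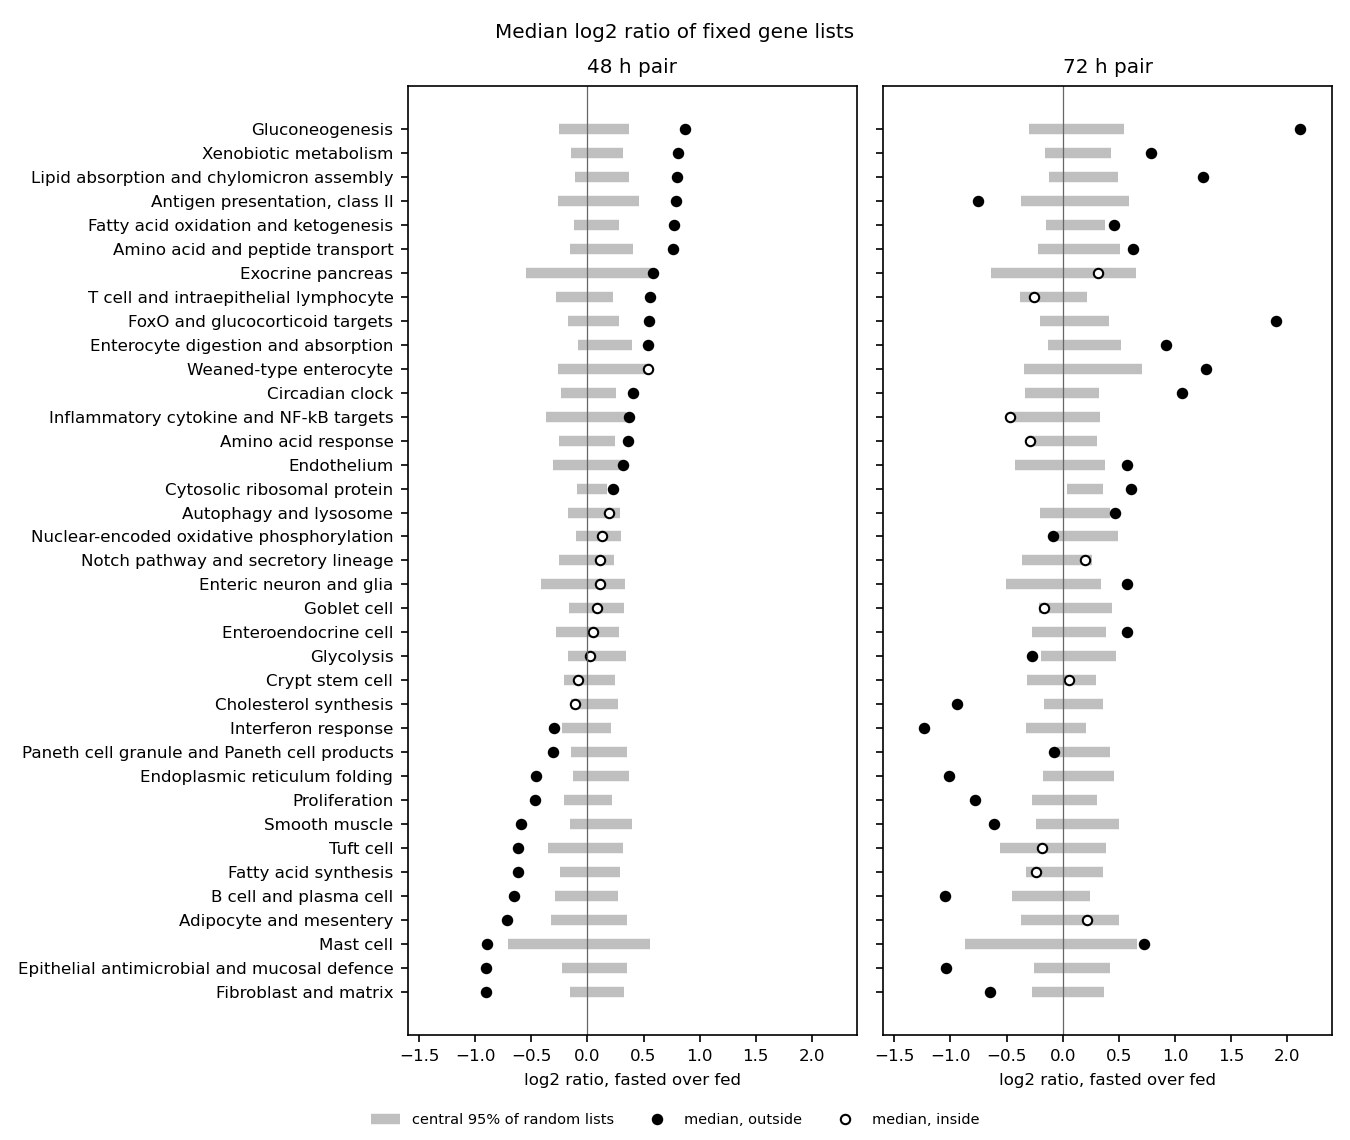
Median log2 ratio, fasted over fed, of the 37 described gene lists in the 48 h pair and the 72 h pair, with grey bars for the central 95% of medians of 10000 random lists matched on size and level, filled points outside it and open points inside. Gluconeogenesis stands at 0.87 and 2.11 and antimicrobial defence at -0.90 and -1.04, while class II antigen presentation lies on opposite sides, at 0.79 and -0.76.

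The pairs were compared to find which differences recurred in a separate preparation and at a longer fast. Metallothioneins, Pck1 and the cytochrome P450 genes Cyp3a11 and Cyp2b10 were higher in both fasted libraries, and gasdermin C, Duox2 and serum amyloid genes lower in both. Among genes above the naming level and ranked by the smaller of their ratios, the highest in both included Mt2, Mt1, Pdk4, Pck1, Cyp3a11, Apod and Cyp2b10. The 8 lowest in both were Gsdmc4, Gsdmc2, Gsdmc3, Duox2, Duoxa2, Saa1, Scd2, which encodes a fatty acid desaturase, and Hsph1, a heat shock protein with log2 ratios of -2.16 and -3.33. Of 11929 genes past the floor in both pairs, 221 were at least 2-fold higher in both, against 23.4 for independent lists of 404 and 691 genes. A further 104 were lower in both, against 17.1 for independent lists of 291 and 702 genes, and 7 differed in opposite directions, against 40.6. With library totals 145 were higher and 208 lower in both.

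Across these genes the log2 ratios had a Pearson correlation of 0.56 and a Spearman correlation of 0.47, and 66.0% had the same sign. Genes are not independent replicates, and the pairs differ in fasting time, preparation and unit at once. Of the 45 fixed lists, 10 lay above and 8 below the random band in both pairs, 2 lay on opposite sides, 14 lay outside in 1 pair, and 3 more were described although they lay outside in neither. The remaining 8 lists lay inside the band in the scaling and floor used here, wherever they could be placed. Some lists share genes, such as Sis in the digestion and weaned-type lists and Per1 in the clock and FoxO and glucocorticoid lists. These counts are therefore not counts of independent lists.

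**Figure D3:**
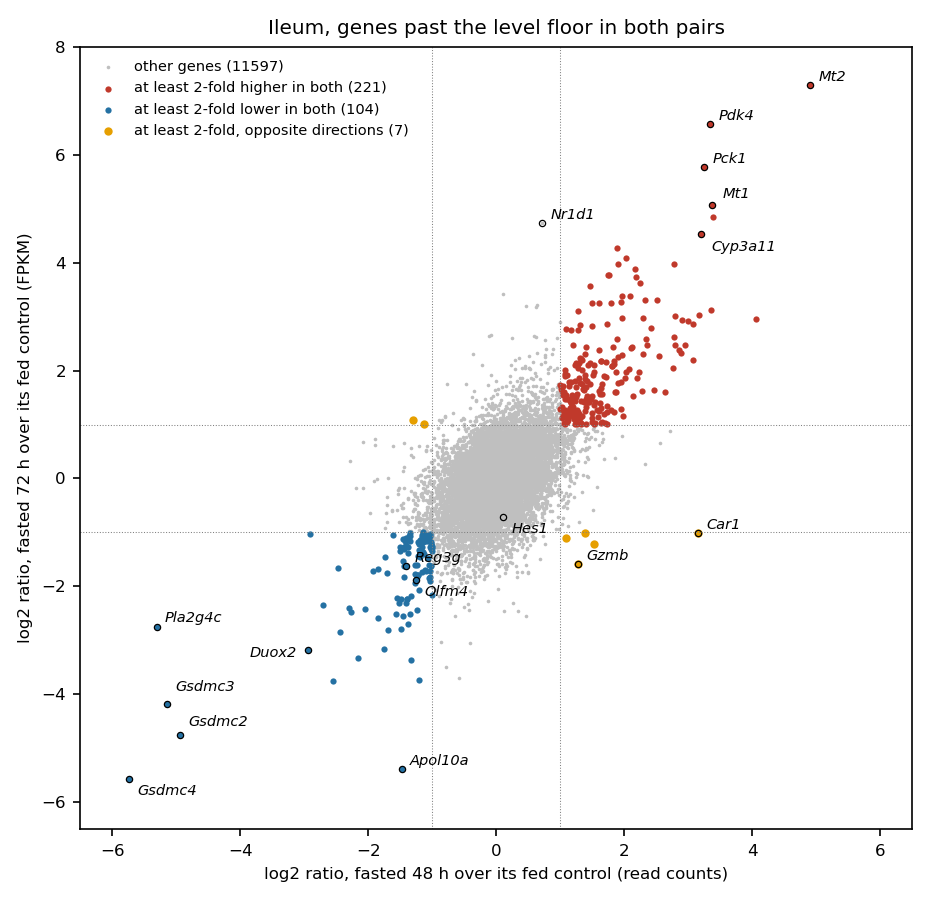
Log2 ratio of each of 11929 genes in the 48 h pair (horizontal axis, read counts) and in the 72 h pair (vertical axis, FPKM), with dotted lines at 2-fold, red points for the 221 genes higher in both, blue for the 104 lower in both and orange for the 7 with opposite directions. Mt2 and Gsdmc4 lie at the far ends, and Hes1 lies at 0.11, or -0.06 with library totals, and -0.71.

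The fed controls were compared with each other to see how far apart libraries with the same label lay. Read counts were divided by transcript length to give a common unit. Of 12588 genes, 1047 differed by at least 2-fold between the fed controls, 739 of them higher in the control of the 72 h pair, with a correlation of log2 levels across genes of 0.90. This was 8.32% of genes, a larger share than the 7.09% within the 48 h pair, and 1495 of 12462 differed within the 72 h pair. Between the fasted libraries 1551 of 12325 genes differed, which was 12.6%. Both counts contain differences of preparation, counting method and unit as well as of animals, which cannot be separated here.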

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

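The tests on B cell genes were chosen only after the result was seen. Each difference between the pairs given here is untested, because each group has 1 library, and each was picked because the fasted library was higher in 1 pair and lower in the other.

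Class II antigen presentation genes had a median log2 ratio of 0.79 at 48 h and -0.76 at 72 h. More B cells in the 48 h fasted tissue is argued against by the B cell and plasma cell genes, whose median was -0.66 (bootstrap interval over genes -1.02 to -0.39), with no gene shared between the lists. At 72 h fewer B cells could account for the lower values, since that median was -1.05 (-1.35 to -0.91). Jchain, an abundant plasma cell gene chosen after its values were seen, had log2 ratios of -0.39 at 48 h (7237 to 4871 reads) and -1.21 at 72 h (402 to 145 FPKM), while Igha, chosen likewise, stood at -0.06 at 48 h (40033 to 33875 reads). A difference between the fed controls cannot be told apart from a response to fasting: the class II median was 0.61 (0.22 to 0.86) in the fed control of 72 h over that of 48 h and -0.97 between the fasted libraries, and an offset between the units could shift both, while a biological effect of fasting time stays open and untested.

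The mast cell list had a median of -0.89 over 4 genes at 48 h and 0.73 over 3 genes at 72 h, and these rest on the floor and pseudocount: without a floor the medians were -0.22 over 7 genes, inside the random band, and 0.19 over 9 genes, and with a pseudocount of 0.1 the 72 h median of 0.80 was inside it. Gzmb, which encodes granzyme B, stood at 1.28 and -1.58. The other 6 genes with opposite differences were chosen after their values were seen. Car1 went from 3 to 83 reads at 48 h, a log2 ratio of 3.16 with the pseudocount (interval without it 3.37 to 7.27), and stood at -1.01 at 72 h. Gstm3 stood at 1.53 and -1.22. Sprr1a stood at 1.38 and -1.01. Socs1, an inhibitor of cytokine signalling, stood at 1.09 and -1.09. Amy1 stood at -1.14 and 1.01. Ptar1 stood at -1.30 and 1.09.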

How the results depend on the processing

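Removal of the length and GC trend was added after the data were seen, and was not run for single genes or for the fed controls. The 48 h count was 616 genes with the floor 5 times higher, where fewer genes were tested, against 986, and from 793 to 1329 under the other alternatives. The 72 h count was 2311 with a pseudocount of 0.1, against 1495, because a smaller pseudocount widens the ratios of low genes, and from 1220 to 1740 under the others. The count in the same direction in both pairs was 1291 at 1.5-fold and 49 at 4-fold, against 325 at 2-fold, as a threshold must move it, and from 260 to 480 under the others at 2-fold. The Paneth cell median at 72 h reversed to 0.014 with the trend removed, against -0.07, and the cause was not tested. Of 54 list medians outside the random band, 45 were outside under each alternative fixed beforehand and 43 with trend removal included. Over 614 recomputed list medians, 557 kept sign and side of the band, 20 went inside it, 8 went outside it and 28 inside it changed sign. Of 268 named gene ratios past 2-fold, 239 were past it under each of the 3 alternatives run for single genes. The other unit of a pair was not run, since no file used here holds both units. Depth limits the genes near the floor most, and no alternative stands in for a replicate.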

Other observations

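The tests on non-epithelial tissue, time of day and glucocorticoid targets were chosen only after the results were seen, and trend removal was added after the data were seen.

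Of the fixed lists inside the random band in both pairs, ileal bile acid handling had medians of 0.18 and 0.49 over 8 genes, with 2 higher in each pair. Fgf15, the ileal hormone that restrains bile acid synthesis, went from 147 to 448 reads at 48 h (log2 ratio 1.73, interval 1.51 to 2.06) and stood at 1.34 at 72 h. Fabp6, the ileal bile acid binding protein, stood at -0.83 and -0.89, and passed 2-fold with library totals, at -1.01 and -1.14. Slc51b, a bile acid exporter subunit, was 1.30 at 72 h. Among translation and mTORC1 genes, with medians of -0.01 and 0.09, the latter -0.14 as deposited, Eif4ebp1, a repressor of cap-dependent translation, stood at 1.07 and 1.27. The elongation factor gene Eef2 stood at 0.77 and 1.05. Macrophage and dendritic cell genes had medians of -0.03 and -0.04 with members in both directions. Cd163 stood at 1.06 and 1.23, Itgam at -1.09 and -1.16, and Adgre1 at -0.68 and -1.34. Aryl hydrocarbon receptor targets had medians of -0.17 and 0.21. At 48 h 2 of 6 were lower, among them Cyp1a1, which went from 94 to 17 reads, while none of 6 passed 2-fold at 72 h. The suckling-period enterocyte medians were 0.36 and 0.37, the neutrophil medians -0.37 and -0.04, and the immediate early and heat shock medians 0.25 and 0.10, the last -0.15 as deposited. The erythrocyte median was 0.63 over 4 genes at 72 h, and lay above the band without a floor. With library totals these medians shifted with all genes, at 72 h to 0.25 for bile acid handling, 0.16 for suckling-period enterocytes, 0.02 for aryl hydrocarbon receptor targets, -0.24 for neutrophils, -0.27 for macrophages and dendritic cells and 0.38 for erythrocytes. At 48 h they shifted to 0.18 for suckling-period enterocytes, 0.075 for immediate early and heat shock genes, -0.20 for macrophages and dendritic cells and -0.34 for aryl hydrocarbon receptor targets, and the bile acid median to 0.00035.

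Fibroblast and matrix genes were lower in both fasted libraries. A trend with transcript length and GC content is argued against as the whole cause, since the median with the trend removed was -0.87 at 48 h (random lists -0.12 to 0.30) and -0.54 at 72 h (-0.27 to 0.34). The endothelial median exceeded the fibroblast median by 1.22 at 48 h (bootstrap interval over genes 0.60 to 1.68) and by 1.22 at 72 h (0.64 to 1.66). With the trend removed the differences were 0.91 (0.58 to 1.37) and 1.11 (0.80 to 1.69), and the endothelial median at 48 h was 0.03. These values argue against an equal loss of all non-epithelial tissue. Genes are not replicates of the tissue, so this holds for these libraries only. The most abundant example named, Col3a1, went from 6356 to 1349 reads at 48 h, and no gene is shared between the fibroblast and endothelial lists. A smaller share of fibroblasts and smooth muscle alone, whose median was -0.60 and -0.61, and an effect of fasting on collagen transcripts may each account for the pattern and stay open, untested.

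Of 18 circadian clock genes in the fixed list, 9 were at least 2-fold higher at 72 h (median 1.06) and 5 at 48 h (median 0.40), a difference between the pairs that was not tested. Another time of day at harvest could account for this, and cannot be told apart from fasting because the labels give no harvest time. Arntl, Npas2, Clock, Cry1 and Nfil3 lay on both sides of 0, with a median of 0.32 (bootstrap interval over genes -0.83 to 0.54). A glucocorticoid response may also account for it and stays open, since 6 of 6 glucocorticoid targets (Fkbp5, Tsc22d3, Zbtb16, Klf15, Sgk1 and Errfi1) were at least 2-fold higher at 48 h as well as at 72 h. They were chosen, after the results were seen, from the fixed list of FoxO and glucocorticoid targets. Of its 20 measured members 9 were higher at 48 h, or 6 with library totals, and 7 lay below 0. That these 6 targets were higher at 48 h too counts against such a response as the whole cause only if clock output was not higher at 48 h. Of Nr1d1, Nr1d2, Dbp, Tef, Hlf, Per3, Ciart and Cry2, 2 of 7 were higher at 48 h (median 0.94) and 8 of 8 at 72 h (median 2.51). These genes were picked after their values were seen, so their difference between the pairs may follow from the choice and decides nothing here. A direct effect of fasting on the clock was not tested.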
